A study of Homo sapiens with 40 samples.

How the data were processed

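Ribosome footprints and mRNA were sequenced from the same 5 conditions of an immortalised human corneal epithelial line, with 4 libraries per condition and assay and 40 libraries in all. Hyperosmotic medium was made by adding 100 mM NaCl to reach 500 mOsm. Per the labels, cycloheximide was present only in the lysis buffer, and footprints came from RNase I digestion of pooled gradient fractions with excision of short fragments from a gel. The deposited values are raw counts of reads per gene symbol, 1 column per library, and each value in the file was a whole number. The submitters' processing notes name cutadapt 1.18, HISAT2 2.1.0, HTSeq 0.11.4 and genome build hg38, without settings. The annotation, the strand setting, the counted feature and the treatment of reads that map to several places are not given in the sources used here. Counts of paralogs, pseudogenes and overlapping or antisense genes are uncertain to that extent.

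Counts were analysed in R 4.3.3. Genes with enough counts were kept by filterByExpr with a minimum count of 10, which left 13906 genes in mRNA, 10581 in footprints and 10458 in both. Libraries were scaled by TMM, within each assay. Changes were tested with edgeR 4.0.16 quasi-likelihood F-tests in a fit of all 20 libraries of an assay. Translational efficiency (TE, called translation in the text) was tested as the footprint change less the mRNA change in a single fit of 40 libraries in 10 groups. The 6 comparisons were 1 h and 6 h against control, 6 h against 1 h, each drug against 6 h, and Torin1 against MeAIB. Adjusted p-values are Benjamini-Hochberg values per comparison and level with a threshold of 0.05. CPM values use the TMM-scaled totals. Genes were classed as changed through mRNA level (mRNA and footprints past the threshold in the same direction, translation not), through translation (translation and footprints past it in the same direction, mRNA not) or offset (mRNA and translation past it in opposite directions, footprints not). The common biological coefficient of variation was 0.129 in mRNA, 0.0745 in footprints and 0.0998 over both.

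A set of 29 gene lists was fixed before the data were examined: osmolyte genes, ion and volume regulators, amino acid transporters, ATF4 targets, uORF stress mRNAs, tRNA synthetases, ribosomal proteins, other TOP mRNAs, initiation factors, ribosome biogenesis, mitochondrial ribosome, oxidative phosphorylation, mitochondrial genome, unfolded protein response, heat shock, immediate early, inflammatory, p53 targets, cholesterol synthesis, NRF2 targets, glycolysis and hypoxia, autophagy and lysosome, polyamine, DNA replication, mitosis, corneal and basal epithelium, epithelial differentiation, stromal markers, and immune and endothelial markers. Of these 28 were tested, since 0 of the 13 mitochondrially encoded genes are in the file. Some genes belong to several lists. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all lists, levels and comparisons. An estimated correlation and fry were run beside it.

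The comparisons, tests, lists, alternatives and the rule for named genes were also chosen before the data were examined. Named genes are, per comparison, the 5 largest rises and 5 largest falls in mRNA (adjusted p under 0.05, a mean of at least 10 CPM in a group, and no overlap between the 4 and 4 libraries). For translation the same number was taken from genes whose footprints also passed in the same direction. To these were added 9 fixed genes (SLC38A2, SLC6A6, SLC5A3, AKR1B1, NFAT5, ATF4, ASNS, EEF2 and RPS6) and, for each list that passed, the 2 members with the smallest adjusted p in its direction and the 2 against it. Left out were symbols that by their form mark clone-based, long noncoding locus, microRNA, small nucleolar, small nuclear (RNU) or antisense (-AS) genes, annotated pseudogenes and sex-linked marker genes. The form of the symbol decided, not the annotated type, so RN7SK (annotated as snRNA) and SNHG12 (annotated as antisense) stayed in. Gene positions and features came from GENCODE v29 on GRCh38, where 24610 of 26484 symbols matched and 19081 had a coding transcript.

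Alternatives were DESeq2 size factors in edgeR, no filter, DESeq2 1.42.0, fits of only the libraries of the 2 conditions, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were the removal of GC trends of mRNA libraries, the omission of the 2 mRNA libraries that stand apart on principal component 2 (Torin1 replicate 4 and MeAIB replicate 3), and the relation between 1 h and MeAIB. Relations across genes are Pearson r and Spearman rho of translation changes, without p-values since genes are not independent. Where comparisons share libraries, unchanged groups were simulated against those libraries and the shared libraries were split. The GC of 5' leaders was computed for leaders of at least 20 bases. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the reported fits, and 0 columns of the file went unused.

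The analysis was tested on simulated data with the fitted levels and spread, 200 changed genes and a ribosomal protein list shifted by -0.5. For 1 h against control, 1.5-fold, 2-fold and 4-fold changes were recovered in 56.7%, 88.1% and 98.5% of genes in mRNA, 65.7%, 92.5% and 98.5% in footprints and 44.8%, 80.6% and 95.5% in translation. For Torin1 the values were 71.6%, 82.1% and 93.9% in mRNA, 55.2%, 79.1% and 93.9% in footprints and 46.3%, 76.1% and 97% in translation. For MeAIB they were 74.6%, 79.1% and 97%, then 56.7%, 88.1% and 97%, then 46.3%, 79.1% and 98.5%. False calls were 3.6% to 6.58% of calls. Most simulated genes were unchanged, whereas in the data at 1 h translation passed for 7105 of 10458 genes. The share of false calls need not hold there. The shifted list passed each time, and 0 to 3 of the 26 or 27 other lists passed. Genes were simulated independently of each other, so this cannot show how often lists pass falsely where members vary together.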

Results

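The data are 40 libraries of an immortalised human corneal epithelial line, 20 of mRNA and 20 of ribosome footprints, from 5 conditions with n = 4 in each assay: control medium, 1 h and 6 h at 500 mOsm, and 6 h at 500 mOsm with Torin1 (250 nM) or MeAIB (5 mM) present for the last 1 h. The mRNA libraries held 21704068 to 38820229 counts each. Footprint libraries held 3985936 to 10579488 counts in control, 864313 to 1649858 at 1 h, 2943599 to 3315363 at 6 h, 1286418 to 1985237 with Torin1 and 2135802 to 3120580 with MeAIB. Structural noncoding RNA here means only RN7SL1, RN7SL2, RPPH1, RN7SK and RMRP. It made up 0.0855 ± 0.00975% (SD, n = 4) of footprint counts in control, 0.4375 ± 0.0703% at 1 h, 0.168 ± 0.0149% at 6 h, 0.321 ± 0.0328% with Torin1 and 0.224 ± 0.0325% with MeAIB. In the mRNA libraries it made up 16.04 ± 0.95% of counts in control, 15.85 ± 1.1% at 1 h and 18.64 ± 1.3% at 6 h. With Torin1 it was 19.66 ± 2.38% and with MeAIB 18.1 ± 0.738%. Values called mRNA in the text thus come from libraries that also hold noncoding RNA. Levels are TMM-scaled CPM (mean ± SD, n = 4), changes are log2 with a standard error, and translation is the footprint change relative to the mRNA change. That standard error was derived from the test, as the size of the change divided by the square root of its quasi-likelihood F statistic. Counts are relative within a library, so a change in total protein synthesis was not measured. The labels do not say whether the replicates are separate cultures, so the p-values measure only the spread between these samples. Key genes in GRCh38 (hg38) are SLC38A2 on chromosome 12 (46358189 to 46372867), NFAT5 on chromosome 16 (69565094 to 69704666), EEF2 on chromosome 19 (3976056 to 3985469), RPS6 on chromosome 9 (19375715 to 19380254) and ATF4 on chromosome 22 (39519695 to 39522685).

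Which mRNAs changed in level, and which in translation, during the first hour of hyperosmotic stress? Footprints rose on SLC38A2, a sodium-coupled neutral amino acid carrier, and on NFAT5, the transcription factor of the osmotic response, while neither mRNA passed the test. SLC38A2 footprints went from 498 ± 34.5 to 1570 ± 80.3 CPM (mRNA 306 ± 16.6 to 345 ± 46.2), a translation change of 1.52 ± 0.15, adjusted p = 2.41e-11. NFAT5 footprints went from 45.8 ± 6.96 to 115 ± 7.6 CPM (translation 1.21 ± 0.177, adjusted p = 2.12e-07). The taurine carrier SLC6A6 (0.90 ± 0.137, adjusted p = 4.09e-07) and the inositol carrier SLC5A3 (0.81 ± 0.197, adjusted p = 0.000465) also rose in translation. Aldose reductase AKR1B1 went the other way, with a fall in footprints from 145 ± 9.18 to 111 ± 13.5 CPM (-0.36 ± 0.15, adjusted p = 0.0309) and translation that did not pass (-0.41 ± 0.203, adjusted p = 0.0717). The AKR1B1 footprint call ended with DESeq2 size factors (adjusted p = 0.157), by DESeq2 (0.156) and without footprint control replicate 1 (0.0543) or 4 (0.0805) or 1 h replicate 2 (0.0809), 3 (0.052) or 4 (0.12). Over all alternatives its adjusted p was 0.000506 to 0.157. The fall in AKR1B1 translation passed with a replicate block (adjusted p = 0.00908), with the block over assays (0.000857), with only the libraries of the 2 conditions fitted (0.000977), with the 2 mRNA libraries apart on principal component 2 left out (0.049), and without mRNA 1 h replicate 2 (0.0485) or footprint 1 h replicate 1 (0.0446), within 0.000857 to 0.17 over all alternatives. The elongation factor EEF2 lost most of its footprints, from 4140 ± 92.7 to 512 ± 28.8 CPM (translation -3.16 ± 0.112, adjusted p = 7.37e-24), and RPS6 fell less (-0.93 ± 0.0936, adjusted p = 3.42e-11).

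Translation rose for 3296 genes and fell for 3809 of 10458, footprints rose for 3702 and fell for 4222 of 10581, and mRNA rose for 412 and fell for 582 of 13906. In mRNA 1633 genes passed with GC trends of the mRNA libraries removed, against 994 in the reported fit. By class, 3052 genes rose and 3328 fell in translation alone, against 57 and 80 that changed in mRNA level with footprints following, while 24 rises and 20 falls of mRNA were offset in footprints. With DESeq2 size factors in place of TMM the median change of all genes moved up by 0.127 in footprints and 0.101 in translation, and rises then outnumbered falls (4190 up and 3821 down in footprints, 3707 up and 3514 down in translation). By DESeq2 they also did (4125 up and 3727 down, and 3683 up and 3445 down), so the excess of falls depends on scaling.

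Deep falls in translation were those of the ubiquitin-conjugating enzyme CDC34 (-5.68 ± 0.399, adjusted p = 2.42e-15, footprints 43.3 ± 2.37 to 1.05 ± 1.63 CPM) and the cold-shock protein YBX1 (-4.83 ± 0.207, adjusted p = 9.68e-22). Translation of DYNC1H1 (2.09 ± 0.206, adjusted p = 2.24e-11), MDN1 (2.14 ± 0.192), PRKDC (2.08 ± 0.186) and RSRP1 (1.91 ± 0.227) rose. The noncoding RNA RMRP also rose (2.18 ± 0.186). It is itself counted in the structural noncoding share, which was higher in the footprint libraries at 1 h.

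Most of the measured regulators of cell volume lost translation. Of 16 ion and volume regulators measured, 1 rose, 12 fell and 3 did not pass (median -1.22, camera adjusted p = 0.000481, and adjusted p = 0.222 with an estimated correlation). The kinase WNK1 fell (-1.97 ± 0.123), while the kinase SGK1 rose (1.28 ± 0.178). Among 70 ribosomal proteins, 7 rose, 56 fell and 7 did not pass (9 and 56 adjusted over the list alone, median -0.65, camera adjusted p = 1.29e-09, and adjusted p = 0.411 with an estimated correlation). RPLP1 (-3.34 ± 0.141) and RPLP0 (-3.21 ± 0.14) fell most, whereas RPL41 (1.12 ± 0.122) and RPS26 (0.76 ± 0.149) rose. Of 21 other mRNAs with a 5' terminal oligopyrimidine (TOP) tract, 3 rose, 16 fell and 2 did not pass (median -0.44, camera adjusted p = 4.39e-07 and 0.0279 with an estimated correlation). The cyclin CCNI fell (-4.25 ± 0.154) and the initiation factor EIF3E rose (0.59 ± 0.162). Reads of ribosomal protein genes and their pseudogenes are hard to place, and how shared reads were counted is not given in the sources used here.

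Many mitochondrial and cell-cycle proteins gained relative translation. Of 75 subunits of oxidative phosphorylation, 52 rose, 8 fell and 15 did not pass (52 and 10 adjusted over the list alone, median 0.44, camera adjusted p = 1.17e-05, and adjusted p = 0.474 with an estimated correlation). COX6C rose by 1.28 ± 0.122 and CYC1 fell (-0.77 ± 0.0972). Of 75 mitochondrial ribosomal proteins, 41 rose, 8 fell and 26 did not pass (median 0.37, camera adjusted p = 0.0014, and adjusted p = 0.395 with an estimated correlation). MRPS28 footprints went from 90.6 ± 4.24 to 206 ± 8.72 CPM, and MRPL37 fell (-2.51 ± 0.134). Of 32 genes of ribosome biogenesis, 21 rose, 2 fell and 9 did not pass (median 0.49, camera adjusted p = 0.000616, and adjusted p = 0.222 with an estimated correlation), with WDR12 at 1.02 ± 0.103 and BOP1 at -2.10 ± 0.172. Of 24 mitosis genes, 18 rose, 2 fell and 4 did not pass (median 0.65, camera adjusted p = 0.00301, and adjusted p = 0.396 with an estimated correlation), with NUSAP1 at 0.96 ± 0.0936 and CCNA2 at -1.14 ± 0.108. Of 24 replication genes, 14 rose, 5 fell and 5 did not pass (median 0.42, camera adjusted p = 0.00638, and adjusted p = 0.294 with an estimated correlation). Their sliding clamp PCNA rose (footprints 689 ± 24.6 to 1560 ± 105 CPM) and the regulator E2F1 fell (-3.41 ± 0.447).

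In mRNA, FOSB and CYR61 were among the immediate early genes that rose. Of 22 measured, 7 rose, 0 fell and 15 did not pass (8 and 2 adjusted over the list alone, median 0.16, camera adjusted p = 5.7e-10 and 0.03 with an estimated correlation). FOSB went from 2.81 ± 0.753 to 15.3 ± 2.25 CPM (2.44 ± 0.146, adjusted p = 8.2e-10) and the matrix protein gene CYR61 rose by 1.06 ± 0.068. In translation 12 rose, 3 fell and 5 did not pass (13 and 3 adjusted over the list alone, median 0.73, camera adjusted p = 0.0186, and adjusted p = 0.382 with an estimated correlation) among 20. Footprints of the phosphatase DUSP1 went from 92.6 ± 10.7 to 298 ± 23.5 CPM, and SRF fell (-2.64 ± 0.276). The spectrin SPTBN1 (1.13 ± 0.0686) and the small nucleolar host gene SNHG12 (1.59 ± 0.156) rose too. The chromatin regulators KMT2D (-1.83 ± 0.0894, adjusted p = 6.35e-11, mRNA 210 ± 13 to 59 ± 5.15 CPM), NSD1 (-1.68 ± 0.126) and TET3 (-1.52 ± 0.0789) fell. ATF4, which drives the integrated stress response, rose slightly in mRNA (0.26 ± 0.0531, adjusted p = 0.00269) but fell in translation (-0.71 ± 0.13, adjusted p = 1.06e-05). Of 24 cholesterol synthesis genes, 4 rose, 0 fell and 20 did not pass (6 and 0 adjusted over the list alone, median 0.12, camera adjusted p = 0.000447, and adjusted p = 0.253 with an estimated correlation), and INSIG1 rose (0.34 ± 0.0785). The largest named rise, of the respiratory chain gene NDUFA3 (2.78 ± 0.751, adjusted p = 0.0258, 0.375 ± 0.201 to 2.49 ± 3.66 CPM), rested on 1 library, at 0.88 (adjusted p = 0.292) without mRNA 1 h replicate 2. That call also ended with a replicate block (0.0755), with only the libraries of the 2 conditions (0.0946) and without mRNA control replicate 2 (0.102), 3 (0.0659) or 4 (0.0629), within 0.00635 to 0.292 over all alternatives. Markers of immune and endothelial cells did not pass (1 of 7 rose, median 0.23, camera adjusted p = 0.0913). In footprints only 2 of those markers were measured.

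**Figure D1:**
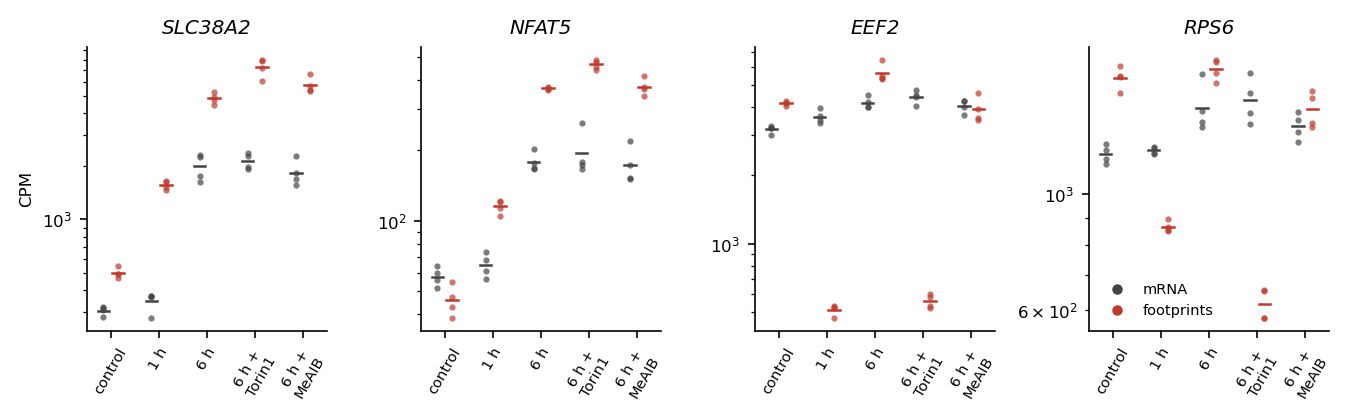
CPM in each library for SLC38A2, NFAT5, EEF2 and RPS6, with mRNA in grey and footprints in red. Bars mark the mean of 4 libraries.

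Which changes marked 6 h of stress against control? In mRNA of 8 osmolyte genes, 7 rose, 0 fell and 1 did not pass (median 1.12, camera adjusted p = 1.33e-06 and 0.0334 with an estimated correlation). SLC38A2 mRNA went from 306 ± 16.6 to 1990 ± 344 CPM (2.70 ± 0.132, adjusted p = 1.64e-12) and its footprints from 498 ± 34.5 to 4820 ± 334 (3.27 ± 0.083, adjusted p = 6.49e-25). NFAT5 rose in mRNA (1.62 ± 0.14, adjusted p = 7.41e-09) and beyond that in translation (1.38 ± 0.162, adjusted p = 2.96e-08). Aldose reductase AKR1B1 (1.31 ± 0.124), SLC6A6 (1.46 ± 0.0878) and SLC5A3 (1.04 ± 0.118) rose in footprints. The mRNA rise of SLC5A3 (0.38 ± 0.115, adjusted p = 0.0102) ended without mRNA 6 h replicate 1 (adjusted p = 0.055), within 0.00421 to 0.055 over all alternatives. ATF4 mRNA rose by 1.70 ± 0.0543, and its translation did not pass (-0.04 ± 0.107, adjusted p = 0.858). EEF2 footprints stood above control (4140 ± 92.7 to 5640 ± 531 CPM).

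In mRNA 3437 genes rose and 3294 fell of 13906, in footprints 2573 rose and 3897 fell of 10581, and in translation 551 rose and 1695 fell of 10458. The excess of falls depended on scaling, with 3237 up and 3339 down in footprints and 1040 up and 1308 down in translation with DESeq2 size factors, and 3129 up and 3157 down and 1100 up and 1321 down by DESeq2. With no filter, 3510 rose and 3497 fell in footprints and 3318 rose and 3448 fell in mRNA, and with only the libraries of the 2 conditions 3605 mRNAs rose and 3723 fell. By class, 1303 genes rose and 1884 fell through mRNA level, 200 rose and 722 fell through translation, and 244 rises and 62 falls of mRNA were offset.

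In footprints of 8 osmolyte genes, 7 rose, 0 fell and 1 did not pass (median 1.32, camera adjusted p = 7.65e-13 and 0.00961 with an estimated correlation). Of 20 immediate early genes, 16 rose, 3 fell and 1 did not pass (median 1.67, camera adjusted p = 2.93e-19 and 0.000376 with an estimated correlation). DUSP1 footprints rose by 2.61 ± 0.0813 and KLF4 mRNA went from 63.1 ± 6.14 to 650 ± 41.2 CPM, while footprints of EGR1 (-1.95 ± 0.142) and MYC (-1.24 ± 0.0757) fell. In mRNA the small GTPase GEM rose from 1.37 ± 0.327 to 38.4 ± 5.69 CPM (4.80 ± 0.213, adjusted p = 3.97e-13), the homeobox gene DLX2 by 4.64 ± 0.164 and FOSB by 4.56 ± 0.149. ARC mRNA went from 0.157 ± 0.142 to 12 ± 2.66 CPM. In footprints of 22 glycolysis and hypoxia genes, 20 rose, 0 fell and 2 did not pass (median 0.55, camera adjusted p = 7.1e-09, and adjusted p = 0.253 with an estimated correlation), among them ADM (3.70 ± 0.178) and VEGFA (3.22 ± 0.0937). Of 15 inflammatory genes, 7 rose, 3 fell and 5 did not pass (median 0.26, camera adjusted p = 0.00154, and adjusted p = 0.19 with an estimated correlation), with NFKBIA at 3.56 ± 0.0884, CCL2 at 4.00 ± 0.25 and CSF3 at -3.62 ± 0.378. In mRNA of 18 ion and volume regulators, 10 rose, 2 fell and 6 did not pass (median 0.36, camera adjusted p = 1.54e-05 and 0.0279 with an estimated correlation), with SGK1 at 2.46 ± 0.12 and ATP1B1 at 1.40 ± 0.058.

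Stress pathways rose in part in footprints, to which the values here refer. Of 27 ATF4 targets, 11 rose, 6 fell and 10 did not pass (12 and 6 adjusted over the list alone, median 0.17, camera adjusted p = 0.000498, and adjusted p = 0.253 with an estimated correlation). ATF3 rose by 3.45 ± 0.144 with VEGFA, which other lists hold too, against DDIT4 (-0.72 ± 0.0959) and XPOT (-0.48 ± 0.0847). Asparagine synthetase ASNS did not pass (0.06 ± 0.252, adjusted p = 0.845). Of 18 amino acid transporters, 8 rose, 4 fell and 6 did not pass (median 0.24, camera adjusted p = 0.023, and adjusted p = 0.3 with an estimated correlation), with SLC1A3 at 0.88 ± 0.092 and SLC3A2 at -0.31 ± 0.0745. Of 21 genes of the unfolded protein response, 14 rose, 2 fell and 5 did not pass (median 0.27, camera adjusted p = 0.00907, and adjusted p = 0.39 with an estimated correlation), with the chaperone HSPA5 at 0.91 ± 0.0705 and the transcription factor XBP1 at -0.58 ± 0.118. Of 17 heat shock genes, 12 rose, 1 fell and 4 did not pass (median 0.38, camera adjusted p = 0.00119, and adjusted p = 0.345 with an estimated correlation), with DNAJB1 at 1.05 ± 0.078 and HSPA8 at -0.66 ± 0.0988. Of 18 NRF2 targets, 10 rose, 2 fell and 6 did not pass (median 0.28, camera adjusted p = 0.0362, and adjusted p = 0.379 with an estimated correlation), PRDX1 rising by 0.82 ± 0.0585. Of 24 cholesterol synthesis genes, 17 rose, 0 fell and 7 did not pass (18 and 0 adjusted over the list alone, median 0.35, camera adjusted p = 4.11e-06, and adjusted p = 0.15 with an estimated correlation), with SQLE at 1.41 ± 0.0691.

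In footprints of 26 initiation factors, 12 rose, 2 fell and 12 did not pass (median 0.16, camera adjusted p = 0.00151, and adjusted p = 0.206 with an estimated correlation), with EIF4A3 at 1.17 ± 0.0566 and the inhibitor EIF4EBP2 at -1.40 ± 0.164. In mRNA of 9 polyamine genes, 6 rose, 1 fell and 2 did not pass (7 and 1 adjusted over the list alone, median 0.33, camera adjusted p = 0.0305, and adjusted p = 0.235 with an estimated correlation), with the catabolic enzyme SAT1 at 1.38 ± 0.0637. Footprints of the replication factor CDT1 rose (0.99 ± 0.093), and of 24 replication genes, 14 rose, 4 fell and 6 did not pass (median 0.24, camera adjusted p = 0.00215, and adjusted p = 0.232 with an estimated correlation). Of 16 corneal and basal epithelial markers, 8 rose, 0 fell and 8 did not pass (median 0.32, camera adjusted p = 0.0152, and adjusted p = 0.582 with an estimated correlation). Footprints of autophagy and lysosome genes moved both ways, 13 up and 3 down of 22 (median 0.26, mean 0.03, camera adjusted p = 0.0655).

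Ribosomal proteins rose in mRNA and fell in part in translation. In mRNA of 79, 75 rose, 1 fell and 3 did not pass (76 and 1 adjusted over the list alone, median 0.36, camera adjusted p = 4.06e-10, and adjusted p = 0.503 with an estimated correlation), with RPS27 at 0.54 ± 0.0659. In translation of 70, 0 rose, 20 fell and 50 did not pass (0 and 26 adjusted over the list alone, median -0.19, camera adjusted p = 0.000356, and adjusted p = 0.629 with an estimated correlation), with RPS12 at -1.20 ± 0.136. Translation fell most for YBX1 (-2.52 ± 0.126, adjusted p = 6.66e-18) and the kinases ADRBK1 (-2.25 ± 0.173) and GRK6 (-2.12 ± 0.131). It rose for periaxin PRX (1.86 ± 0.43) and NUFIP2 (1.22 ± 0.163) besides NFAT5. The mRNAs that fell furthest encode the mitochondrial synthetases PARS2 (-4.08 ± 0.161, adjusted p = 7.2e-14, 13 ± 1.64 to 0.765 ± 0.0999 CPM) and MARS2 (-2.88 ± 0.163), the arrestin ARRDC3 (-2.95 ± 0.136), CCDC71 (-2.95 ± 0.0974) and TMEM177 (-2.95 ± 0.108).

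What changed between 1 h and 6 h? EEF2 and VIM, which had few footprints at 1 h, rose by 6 h. EEF2 footprints went from 512 ± 28.8 to 5640 ± 531 CPM (translation 3.22 ± 0.112, adjusted p = 5e-24) and vimentin VIM from 419 ± 66 to 6110 ± 342 (translation 3.49 ± 0.122, adjusted p = 5e-24). SLC38A2 mRNA rose by 2.53 ± 0.131 while its translation fell (-0.95 ± 0.149, adjusted p = 1.07e-06), and SLC6A6 translation fell by a smaller amount (-0.65 ± 0.134, adjusted p = 7.81e-05). NFAT5 mRNA rose (1.46 ± 0.139) and its translation did not pass (0.17 ± 0.169, adjusted p = 0.389). ATF4 (0.67 ± 0.129) and RPS6 (0.69 ± 0.0936) rose in translation.

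In mRNA 3199 genes rose and 3230 fell of 13906, in footprints 4079 rose and 3727 fell of 10581, and in translation 3202 rose and 2855 fell of 10458. Translation rose for CDC34 (5.33 ± 0.415) and the receptor phosphatase PTPRF (3.86 ± 0.235). It fell for coilin COIL (-2.49 ± 0.185) and DYNC1H1 (-2.13 ± 0.209). The noncoding RN7SK fell by 3.02 ± 0.418, and it is itself counted in the noncoding share of footprints, which dropped. In mRNA the transcription factors KLF5 (3.62 ± 0.0998) and CSRNP1 (3.56 ± 0.0893) rose and C1orf74 fell (-2.86 ± 0.193). In footprints of 16 ion and volume regulators, 13 rose, 1 fell and 2 did not pass (median 1.76, camera adjusted p = 3.78e-07, and adjusted p = 0.208 with an estimated correlation). In translation of 70 ribosomal proteins, 43 rose, 7 fell and 20 did not pass (44 and 7 adjusted over the list alone, median 0.43, camera adjusted p = 3.56e-07, and adjusted p = 0.503 with an estimated correlation), RPLP1 rising by 2.90 ± 0.143. Of 21 other TOP mRNAs, 14 rose, 2 fell and 5 did not pass (median 0.42, camera adjusted p = 1.9e-09 and 0.00735 with an estimated correlation).

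Most mitochondrial proteins of the lists lost relative translation. Of 75 subunits of oxidative phosphorylation, 8 rose, 47 fell and 20 did not pass (9 and 49 adjusted over the list alone, median -0.49, camera adjusted p = 6.37e-07, and adjusted p = 0.407 with an estimated correlation), with NDUFS4 at -1.17 ± 0.109. Of 75 mitochondrial ribosomal proteins, 6 rose, 47 fell and 22 did not pass (6 and 49 adjusted over the list alone, median -0.37, camera adjusted p = 1.05e-05, and adjusted p = 0.222 with an estimated correlation), with MRPS28 at -1.12 ± 0.0987. In footprints of 24 mitosis genes, 4 rose, 18 fell and 2 did not pass (median -0.65, camera adjusted p = 6.06e-05, and adjusted p = 0.206 with an estimated correlation), with CDK1 at -1.16 ± 0.0649. Some epithelial proteins gained in translation. Of 16 corneal and basal markers, 8 rose, 1 fell and 7 did not pass (median 0.57, camera adjusted p = 0.0387, and adjusted p = 0.602 with an estimated correlation), with the integrin ITGB4 at 3.05 ± 0.205 and keratin KRT5 at 2.06 ± 0.141, against the connexin GJA1 (-1.20 ± 0.098). Of 7 differentiation genes, 4 rose, 0 fell and 3 did not pass (median 0.44, camera adjusted p = 0.0463, and adjusted p = 0.335 with an estimated correlation), and KRT17 footprints went from 67.9 ± 5.2 to 683 ± 79 CPM.

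What did Torin1, an inhibitor of the kinase mTOR, do in the last hour of the 6 h stress? Translation fell for most mRNAs of ribosomal proteins and most other TOP mRNAs. EEF2 footprints went from 5640 ± 531 to 559 ± 37.9 CPM (translation -3.40 ± 0.111, adjusted p = 1.3e-24), and RPS27 (-3.64 ± 0.238), RPL12 (-3.42 ± 0.168), RPL28 (-2.93 ± 0.125) and EEF1A1 (-2.86 ± 0.215) also fell. RPS6 fell by 1.52 ± 0.094. Of 70 ribosomal proteins, 0 rose, 64 fell and 6 did not pass (0 and 68 adjusted over the list alone, median -1.64, camera adjusted p = 7.28e-09 with an estimated correlation). Of 21 other TOP mRNAs, 0 rose, 20 fell and 1 did not pass (median -1.30, camera adjusted p = 6.45e-106 and 1.45e-12 with an estimated correlation), with EIF2S3 at -1.61 ± 0.0694. SLC38A2 footprints rose further, from 4820 ± 334 to 7280 ± 870 CPM (0.59 ± 0.0759, adjusted p = 2.81e-07), as did those of NFAT5 (0.34 ± 0.0719, adjusted p = 0.000543) and SLC6A6 (0.37 ± 0.088, adjusted p = 0.00193). Translation of NFAT5 did not pass (0.24, adjusted p = 0.347). It passed with the 2 mRNA libraries apart on principal component 2 left out (0.40, 0.0126), within 0.0126 to 0.655 over all alternatives. Translation fell for 877 genes and rose for 688 of 10458, and footprints fell for 1435 and rose for 1431 of 10581.

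The translation call of SLC38A2 (0.51 ± 0.147, adjusted p = 0.0153) ended with no filter (0.44, adjusted p = 0.0568), with only the libraries of the 2 conditions (0.47, 0.0544) and without mRNA 6 h replicate 1 (0.0503) or footprint Torin1 replicate 1 (0.0621) or 3 (0.0624), within 0.00389 to 0.0624 over all alternatives. Footprints of ATF4 did not pass (0.22, adjusted p = 0.0617, within 0.0161 to 0.217 over all alternatives). Its translation call (0.38 ± 0.107, adjusted p = 0.0115) ended with no filter (0.32, adjusted p = 0.0593) and without footprint Torin1 replicate 2 (0.0544), within 0.0034 to 0.0593 over all alternatives. Of 10 stress mRNAs with upstream reading frames, 6 rose, 0 fell and 4 did not pass (median 0.48, camera adjusted p = 0.00597, and adjusted p = 0.14 with an estimated correlation), among them IFRD1 (0.54 ± 0.138) and PPP1R15B (0.49 ± 0.0874). DYNC1H1 (1.68 ± 0.209, adjusted p = 6.62e-08) and PRKDC (1.32 ± 0.186) rose, as did the noncoding TERC (1.16 ± 0.304) where the noncoding share of footprints was higher. Of 20 immediate early genes, 4 rose, 0 fell and 16 did not pass (6 and 0 adjusted over the list alone, median 0.27, camera adjusted p = 0.0206, and adjusted p = 0.395 with an estimated correlation), with CYR61 at 0.45 ± 0.108. Of 18 tRNA synthetases, 0 rose, 4 fell and 14 did not pass (median -0.17, camera adjusted p = 0.00335, and adjusted p = 0.112 with an estimated correlation), with QARS at -1.17 ± 0.0908. Of 75 subunits of oxidative phosphorylation, 1 rose, 23 fell and 51 did not pass (1 and 29 adjusted over the list alone, median -0.14, camera adjusted p = 2.72e-05, and adjusted p = 0.503 with an estimated correlation), with ATP5G2 at -1.09 ± 0.0972. Of 18 NRF2 targets, 1 rose, 7 fell and 10 did not pass (1 and 9 adjusted over the list alone, median -0.20, camera adjusted p = 0.000616, and adjusted p = 0.215 with an estimated correlation), with TKT at -1.78 ± 0.115 and FTL at -1.62 ± 0.162 against TXNRD1 (0.47 ± 0.105). Footprints of the keratins KRT17 (-1.29 ± 0.104) and KRT6A (-1.17 ± 0.0942) fell, and of 7 differentiation genes, 0 rose, 2 fell and 5 did not pass (median -0.62, camera adjusted p = 0.0179, and adjusted p = 0.148 with an estimated correlation).

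Few mRNAs changed with Torin1. By edgeR 8 rose and 0 fell of 13906, with 710 at an unadjusted p under 0.05 and 31 past the threshold by DESeq2. Ribosomal RNA28S5 (2.18 ± 0.282, adjusted p = 0.00122) and SPTBN1 (0.52 ± 0.0682, adjusted p = 0.00122) rose. Each of these 2 reached an adjusted p of 0.0548 when only the libraries of the 2 conditions were fitted, where 1 gene passed, a fall. Thus 0 of the 8 rises passed in that fit. Over all alternatives the adjusted p was 2.85e-09 to 0.0548 for RNA28S5 and 6.75e-08 to 0.0548 for SPTBN1. Without 6 h replicate 1 or 3 the count was 5 or 4, and without Torin1 replicate 1 or 3 it was 5. The mRNA library Torin1 replicate 4 lay at -36.39 on principal component 2, and the others of its group at 1.344 to 12. Stromal markers did not pass (7 measured, 0 called, 0 adjusted over the list alone, median -0.06, camera adjusted p = 0.242).

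What did MeAIB, a substrate that competes for the SLC38A2 carrier, do in the same hour? Translation mostly fell, for 526 genes, and rose for 39 of 10458. The adenylyl cyclase ADCY3 fell furthest (-2.00 ± 0.215, adjusted p = 1.13e-07, footprints 24.9 ± 4.09 to 6.48 ± 2.74 CPM), followed by SBF1 (-1.47 ± 0.198) and the zinc finger ZNF496 (-1.36 ± 0.173). EEF2 fell moderately (-0.50 ± 0.107, adjusted p = 0.00243), while DYNC1H1 (1.05 ± 0.209, adjusted p = 0.00111), PRKDC (0.86 ± 0.185) and RPL7L1 (0.90 ± 0.199) rose. SLC38A2 footprints rose from 4820 ± 334 to 5760 ± 601 CPM (0.26 ± 0.0756, adjusted p = 0.0185), and its translation did not pass (0.37 ± 0.147, adjusted p = 0.154). That translation rise passed without mRNA MeAIB replicate 3 (0.48, adjusted p = 0.0357) and with the 2 mRNA libraries apart on principal component 2 left out (0.48, 0.0253), within 0.0253 to 0.335 over all alternatives. The footprint call ended without footprint 6 h replicate 2 (adjusted p = 0.0721) or MeAIB replicate 1 (0.106), within 9.5e-05 to 0.106 over all alternatives. Footprints fell for 1196 genes and rose for 483 of 10581. Without footprint MeAIB replicate 4 the calls dropped to 347 in translation and 992 in footprints.

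In translation of 16 ion and volume regulators, 0 rose, 3 fell and 13 did not pass (0 and 5 adjusted over the list alone, median -0.27, camera adjusted p = 0.00327, and adjusted p = 0.319 with an estimated correlation), with the channel subunit LRRC8A at -0.77 ± 0.147 and WNK1 at -0.41 ± 0.0981. In footprints of 70 ribosomal proteins, 0 rose, 25 fell and 45 did not pass (1 and 28 adjusted over the list alone, median -0.14, camera adjusted p = 9.08e-07, and adjusted p = 0.382 with an estimated correlation), with RPLP0 at -0.62 ± 0.0805. The median of this list was below 0 in mRNA too, as given under other observations, so the footprint values alone do not show a fall in translation. Translation of RPS6 passed in no alternative (adjusted p = 0.201 to 0.693). Medians for mitochondria and ribosome biogenesis were slightly above 0 in translation, and few members passed. Of 75 mitochondrial ribosomal proteins, 3 rose, 0 fell and 72 did not pass (0 and 0 adjusted over the list alone, median 0.09, camera adjusted p = 5.94e-06, and adjusted p = 0.222 with an estimated correlation). Of 75 subunits of oxidative phosphorylation, 2 rose, 0 fell and 73 did not pass (0 and 0 adjusted over the list alone, median 0.11, camera adjusted p = 5.42e-08, and adjusted p = 0.379 with an estimated correlation). Of 32 ribosome biogenesis genes, 0 rose, 0 fell and 32 did not pass (median 0.09, camera adjusted p = 0.00191, and adjusted p = 0.269 with an estimated correlation). In footprints of 24 mitosis genes, 9 rose, 0 fell and 15 did not pass (11 and 0 adjusted over the list alone, median 0.12, camera adjusted p = 2.87e-05, and adjusted p = 0.177 with an estimated correlation), with CENPE at 0.81 ± 0.0915 and TOP2A at 0.48 ± 0.0889. Of 20 immediate early genes, 8 rose, 2 fell and 10 did not pass (11 and 3 adjusted over the list alone, median 0.22, camera adjusted p = 0.000995, and adjusted p = 0.17 with an estimated correlation), with CYR61 at 0.79 ± 0.0736, KLF4 at -0.62 ± 0.105 and SRF at -0.92 ± 0.166. Of 10 stress mRNAs with upstream frames, 3 rose, 0 fell and 7 did not pass (median 0.17, camera adjusted p = 0.0344, and adjusted p = 0.308 with an estimated correlation), PPP1R15A rising by 0.91 ± 0.127. Of 21 p53 targets, 3 rose, 2 fell and 16 did not pass (3 and 3 adjusted over the list alone), and the list did not pass (median 0.07, camera adjusted p = 0.189).

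In mRNA 48 genes rose and 17 fell by edgeR. In all, 199 passed by DESeq2, 321 with GC trends of mRNA libraries removed, 178 with a replicate block and 45 with no filter. The deubiquitinase TNFAIP3 (0.78 ± 0.118, adjusted p = 0.00412), PPP1R15A (0.65 ± 0.0956, adjusted p = 0.00398) and CYR61 (0.52 ± 0.067, adjusted p = 0.00145) rose and kept the call without any single library and with only the libraries of the 2 conditions fitted, where 9 genes passed. Of 20 inflammatory genes, 1 rose, 0 fell and 19 did not pass (9 and 0 adjusted over the list alone, median 0.48, camera adjusted p = 1.54e-08, and adjusted p = 0.0602 with an estimated correlation). The count was 12, 32 and 8 without mRNA 6 h replicates 1, 2 and 3, and 30, 22, 28 and 28 without mRNA MeAIB replicates 1, 2, 3 and 4. The mRNA library MeAIB replicate 3 lay at -31.46 on principal component 2, and the others of its group at -2.445 to 15.3.

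How did the drugs differ from each other? Translation of EEF2 and of most ribosomal proteins was lower with Torin1 than with MeAIB. EEF2 was lower (-2.90 ± 0.111, adjusted p = 3.6e-22), as were RPS27 (-3.54 ± 0.242), RPL12 (-2.99 ± 0.174) and RPS6 (-1.38 ± 0.0941). ADCY3 (2.07 ± 0.23, adjusted p = 4.5e-09), PPP1R9B (1.91 ± 0.233) and FZD5 (1.88 ± 0.327) were higher. ATF4 was higher in translation (0.47 ± 0.108, adjusted p = 0.00119), as was SLC6A6 (0.51 ± 0.126, adjusted p = 0.00256). SLC38A2 footprints were higher (0.34 ± 0.0757, adjusted p = 0.00085), and its translation did not pass (0.14 ± 0.147, adjusted p = 0.574). Translation was higher for 1429 genes and lower for 855 of 10458, and footprints for 1903 and 1245 of 10581. With no filter the lower genes outnumbered the higher ones (904 higher and 1044 lower in translation, 1513 and 1538 in footprints), and with only the libraries of the 2 conditions 803 were higher and 804 lower in translation.

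Here rose and fell mean higher and lower with Torin1. Of 70 ribosomal proteins, 0 rose, 66 fell and 4 did not pass (0 and 67 adjusted over the list alone, median -1.60, camera adjusted p = 1.34e-292 and 5.76e-08 with an estimated correlation). Of 16 ion and volume regulators, 5 rose, 0 fell and 11 did not pass (median 0.22, camera adjusted p = 0.0119, and adjusted p = 0.396 with an estimated correlation), with LRRC8A at 1.17 ± 0.15 and WNK1 at 1.00 ± 0.0988. Of 18 tRNA synthetases, 0 rose, 7 fell and 11 did not pass (median -0.21, camera adjusted p = 8.79e-05 and 0.0235 with an estimated correlation), with QARS at -1.13 ± 0.0914. Of 26 initiation factors, 2 rose, 8 fell and 16 did not pass (3 and 9 adjusted over the list alone, median -0.20, camera adjusted p = 0.00132 and 0.0428 with an estimated correlation), with EIF3G at -0.83 ± 0.0909. Of 17 heat shock genes, 0 rose, 3 fell and 14 did not pass (median -0.10, camera adjusted p = 0.0171, and adjusted p = 0.379 with an estimated correlation), with HSPA8 at -1.31 ± 0.158. In footprints of 75 subunits of oxidative phosphorylation, 0 rose, 39 fell and 36 did not pass (0 and 43 adjusted over the list alone, median -0.22, camera adjusted p = 2.73e-11 and 0.0334 with an estimated correlation). In footprints of 22 glycolysis and hypoxia genes, 4 rose, 8 fell and 10 did not pass (5 and 9 adjusted over the list alone, median -0.19, camera adjusted p = 0.00903, and adjusted p = 0.617 with an estimated correlation), with GAPDH at -1.25 ± 0.075. KLF4 (1.28 ± 0.152) and SRF (1.07 ± 0.203) were higher in translation. In mRNA 12 genes were higher and 42 lower by edgeR, 152 by DESeq2 and 0 with only the libraries of the 2 conditions fitted. The count was 5, 23 and 113 without mRNA Torin1 replicates 1, 3 and 4, and 21, 4, 32 and 6 without mRNA MeAIB replicates 1, 2, 3 and 4.

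**Figure D2:**
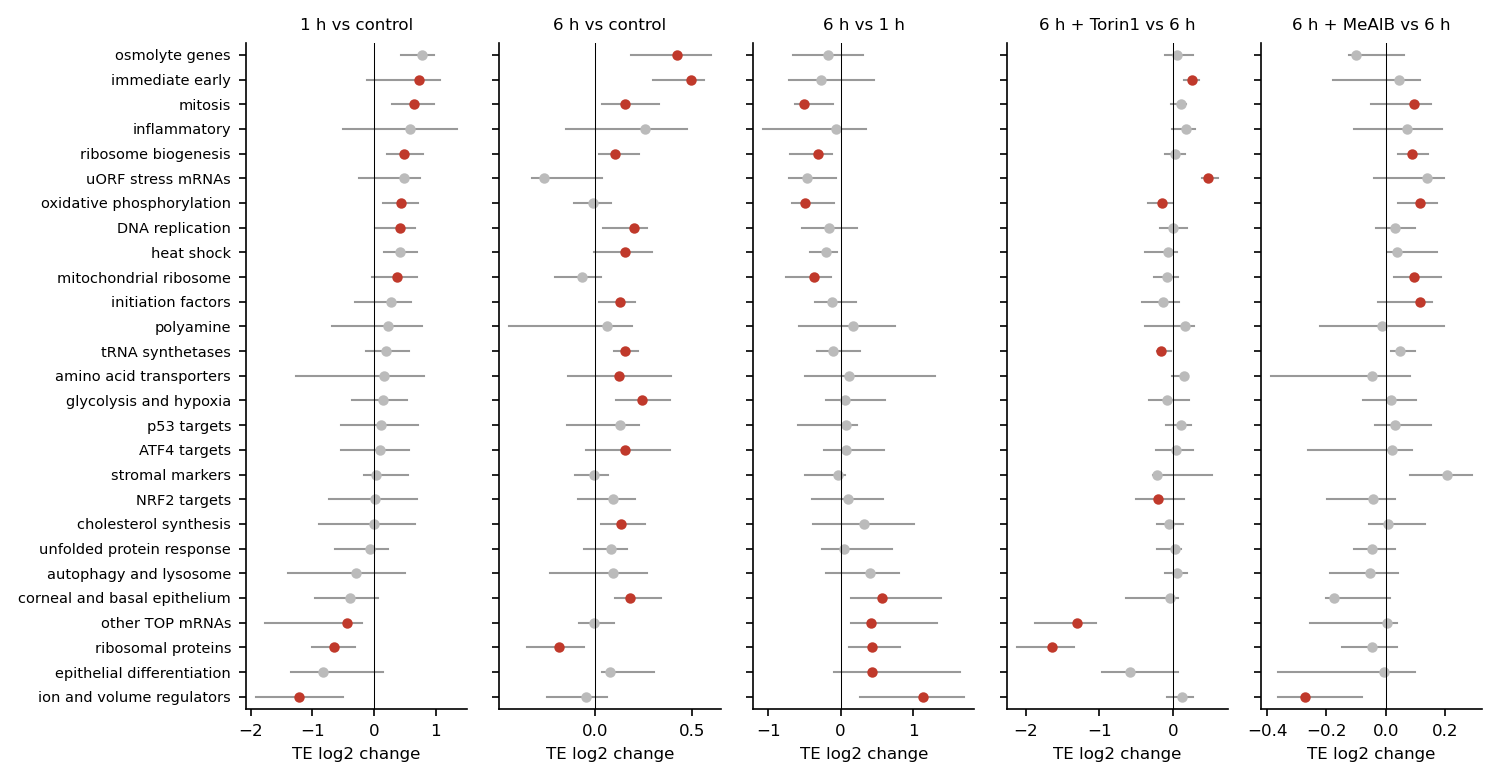
Median translation change of each gene list with its quartiles in 5 comparisons, on a separate scale per panel. Red marks a camera adjusted p under 0.05 with the preset correlation.

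Did the drugs move the same genes as the early stress? Relations are across 10458 genes, which are not independent, and form a family of 3 planned relations and 1 added after the data were seen. Changes in translation at 1 h and with Torin1 were weakly related (r = 0.194, rho = 0.172, covariance 0.101). EEF2 fell in both, and 597 falls were shared where 319 would be if independent. Of the 688 genes that rose with Torin1, 242 had risen at 1 h (217 if independent) and 289 had fallen (251), so the rises show no shared direction. Of the 877 that fell, 116 had risen (276). The added relation of 1 h and MeAIB had r = 0.633 (rho = 0.653, covariance 0.253). Of the 526 genes that fell with MeAIB, ADCY3 and WNK1 among them, 521 had fallen at 1 h (192 if independent), and of the 39 that rose, DYNC1H1 and PRKDC among them, 35 had risen (12 if independent). With no filter on counts, which adds genes with few reads, r was 0.0569 for Torin1 and 0.092 for MeAIB. For MeAIB it was 0.781 in genes at 10 CPM or more in both assays and 0.403 with equal footprint depth. The relation with Torin1 was not thinned, so the difference between the drugs is not taken as settled. These relations share no library.

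Changes at 1 h and 6 h share the control libraries (r = 0.572, rho = 0.555, covariance 0.315). Simulated groups without change against those controls gave r = 0.35 (0.296 to 0.435) and covariance 0.0214, a covariance difference of 0.294, and with the controls split r was 0.532 to 0.547. Shared falls numbered 1405 (617 if independent), YBX1 among them, and shared rises 407 (174), NFAT5 and SLC38A2 among them. Torin1 and MeAIB share the 6 h libraries (r = 0.224, rho = 0.177, covariance 0.0327). There the simulation gave r = 0.41 and covariance 0.0331, a difference of -0.000364, and split libraries gave r of -0.0142 to 0.0935. Shared falls numbered 120 (44 if independent) and shared rises 13 (3). The figures for independent lists leave out the shared libraries, so the excess over them is no measure of a shared effect.

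**Figure D3:**
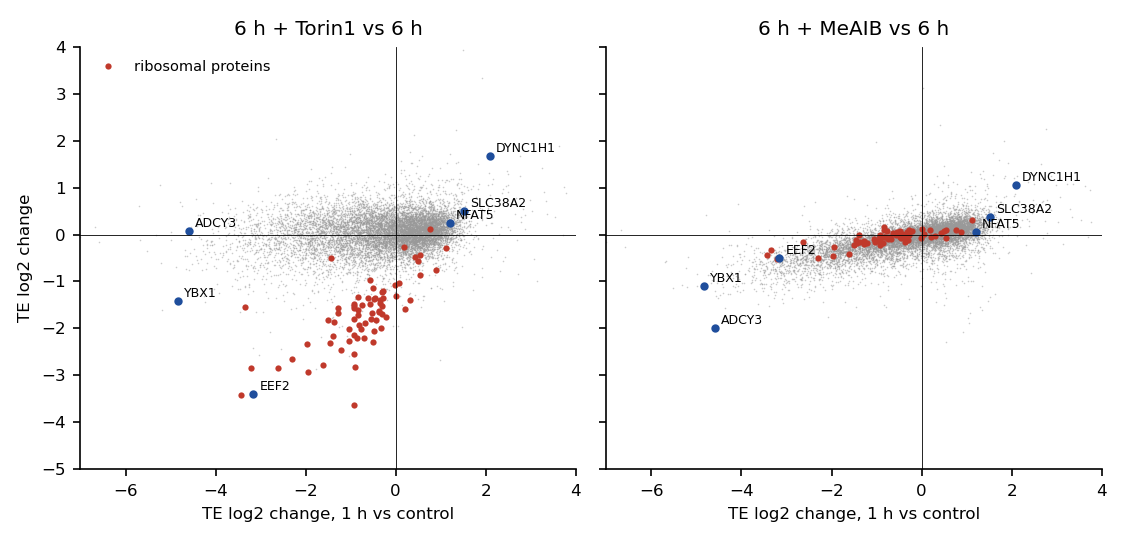
Translation change at 1 h against that with Torin1 and with MeAIB for each gene, with ribosomal proteins in red and 6 named genes in blue.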

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

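Chosen only after the result was seen were the tests of coding-sequence GC and of footprints alone for the pattern of leader GC, the test of footprints for genes with 1 coding exon, and the relation of MeAIB with 1 h.

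Some libraries lay far from the other 3 of their group. Chance flags about 1 in 20 groups, and 120 groups were tested. Footprint control replicate 2 held 10.58 M counts (others 3.986 to 4.861 M). SLC38A2 mRNA was 276.2 CPM in 1 h replicate 4 (364 to 370.9). SLC5A3 mRNA was 71.09 CPM in 6 h replicate 1 (53.69 to 56.43). AKR1B1 was 392.9 CPM in mRNA of Torin1 replicate 1 (274.8 to 284.2) and 439.8 in footprints of 6 h replicate 1 (323.1 to 341.3). NFAT5 mRNA was 261.7 CPM in Torin1 replicate 4 (166 to 178.3). ASNS stood out in Torin1 replicate 3 in mRNA (171.6 CPM, others 66.57 to 78.08) and footprints (357.4, others 155.9 to 166.1), and in footprints of control replicate 3 (174.3, others 104.6 to 115.8). EEF2 footprints were 468.5 CPM in 1 h replicate 3 (522.9 to 529) and 6434 in 6 h replicate 2 (5318 to 5462).

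Direct tests of the difference between conditions set these genes apart. Between 6 h and 1 h they were 6429 in mRNA, 7806 in footprints and 6057 in translation. Between Torin1 and MeAIB they were 54 in mRNA, 3148 in footprints and 2284 in translation.

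First, translation at 1 h fell in genes with GC-rich 5' leaders. Its median change was 0.44 in the 1908 genes with the lowest leader GC (928 up and 373 down) and -1.16 in the 1908 with the highest (122 up and 1356 down), with rho = -0.456 (-0.459 to -0.452 without any single library) across genes. A GC bias acting through the coding sequence is argued against by the median rho of -0.379 (-0.387 to -0.375) within bins of like coding GC, and trends of the mRNA libraries by the rho of -0.456 (-0.458 to -0.45) for footprints alone. Lower depth at 1 h is argued against by the rho of -0.448 (-0.45 to -0.446) with every footprint library thinned to 864313 counts. The change at 1 h also followed GC of the coding sequence (rho = -0.403), the 3' untranslated region (-0.348) and the whole transcript (-0.41). For leader GC rho was -0.243 at 6 h against control, -0.307 with MeAIB and -0.152 with Torin1, so the trend was not confined to 1 h. Between 6 h and 1 h it was 0.431, and between the drugs 0.0815. A hypothesis is that translation from GC-rich leaders may be more sensitive to early osmotic stress, which remains untested as an effect of the stress. A footprint bias tied to the leader itself stays open.

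Second, mRNAs with 1 coding exon were lower at 6 h than at control. Of 714 such genes 130 rose and 367 fell (median -0.42), against a median of 0.03 in 7070 genes with 8 or more coding exons, a difference of -0.448 (-0.464 to -0.431 without any single library). A bias of the mRNA libraries that footprints do not share is argued against by the footprint difference of -0.625 (-0.663 to -0.601). GC, length and expression level as the whole account are argued against by a coefficient of -0.532 (-0.541 to -0.523) with those terms in the model. A candidate explanation is a shorter life of these mRNAs under stress, which was not tested and stays open with any other effect of the 6 h condition.

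Last, translation changes with MeAIB resembled those at 1 h. Trends with GC and length common to both are argued against by r = 0.551 (0.499 to 0.564 without any single library) after removing them, and trends of the mRNA libraries by r = 0.64 (0.583 to 0.646) for footprints alone. The test of equal depth could not tell lower footprint depth at 1 h and with MeAIB from a shared response. With equal depth r was 0.403 (0.384 to 0.421), a range that reaches below the bound of 0.4 set beforehand. Thinning also adds counting noise, which lowers r by itself. Torin1 footprint libraries held fewer counts (1286418 to 1985237) than MeAIB libraries (2135802 to 3120580), and the relation of Torin1 with 1 h had r = 0.194. That relation was not thinned. With equal depth 147 to 209 genes changed in translation with MeAIB. A shared response of the cells may remain as a hypothesis, untested beyond these values.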

How the results depend on the processing

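The tests with GC trends of mRNA libraries removed, with the 2 mRNA libraries apart on principal component 2 left out, and of the relation between 1 h and MeAIB were chosen only after the result was seen. No named gene, list or relation past its threshold reversed its direction under the alternatives run for it. Reversal was not checked for the other genes. The larger of the up and down counts changed side in some alternatives. The report gives this for 1 h, 6 h and Torin1 against MeAIB. In mRNA between 1 h and 6 h the nearly equal counts also did (3239 up and 3190 down with DESeq2 size factors), as did footprints with Torin1 with a replicate block (1719 up and 1578 down) and mRNA with Torin1 with only the libraries of the 2 conditions (0 up and 1 down). Counts of genes stayed within 1.5 times of those reported except as follows, and the cause was not tested. In mRNA at 1 h, 1633 genes passed with GC trends removed. In mRNA with Torin1, 1 passed with only the libraries of the 2 conditions, 31 by DESeq2, 24 with GC trends removed, and 4 (without 6 h replicate 3) to 8 without single libraries. In mRNA with MeAIB, the counts were 9, 199, 321, and 8 (without 6 h replicate 3) to 48 (without 6 h replicate 4). For Torin1 against MeAIB in mRNA they were 0, 152, 145, and 4 (without MeAIB replicate 2) to 113 (without Torin1 replicate 4), with 23 under no filter. With MeAIB, footprints gave 992 (without footprint MeAIB replicate 4) to 1645 and translation 347 (without the same library) to 681. Leaving out those 2 mRNA libraries gave 9, 63 and 56 genes in the drug comparisons of mRNA. The relation of 1 h with Torin1 had r = 0.0569 with no filter, that of 1 h with 6 h had 0.392 with no filter and 0.634 at 10 CPM or more, that of Torin1 with MeAIB had 0.412 with no filter, and that of 1 h with MeAIB had 0.092 with no filter and 0.781 at 10 CPM or more.

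Of 492 list tests 178 passed, 25 of them with an estimated correlation, and 270 passed by fry. With DESeq2 size factors 5 more list tests passed and 0 were lost. Named genes lost 15 calls with DESeq2 size factors, 31 with no filter, 45 with only the libraries of the 2 conditions and 11 by DESeq2. Leaving out single libraries left 7286 gene results on their side of the threshold, ended 345 calls and added 17. The smallest footprint library, at 1 h, held 864313 counts, and in simulated data 44.8% to 46.3% of 1.5-fold changes in translation were recovered.

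Replicate numbers recur across conditions, but the labels do not say that they mark shared cultures, and the check did not pair the samples, since the correlation of deviations exceeded 0.1 in 17 of 40 same-number pairs in mRNA, 16 of 40 in footprints and 17 of 20 between the mRNA and footprint library of a condition and number. As a hint from the data, 16 of 20 mRNA libraries, 20 of 20 footprint libraries and 16 of 20 across assays were closest to their own number. The check thus does not exclude a pairing by number, which the reported fits leave out. With a replicate block, 178 genes passed in mRNA with MeAIB and 132 for Torin1 against MeAIB, while the other counts stayed within 1.5 times. The block added 13 list calls and ended 1, and added 7 calls of named genes and ended 1. With the replicate block over assays, which pairs the mRNA and footprint library, all 6 counts in translation stayed within 1.5 times. Translation of ASNS (0.50 at 1 h, adjusted p = 9.22e-05, and 0.33 at 6 h, 0.0102) and AKR1B1 (-0.41, 0.000857, and 0.29, 0.0178) then passed, and that of COX7A2 (0.0558) and MRPS28 (0.058) with MeAIB did not. Over all alternatives at 1 h the adjusted p was 9.22e-05 to 0.646 for ASNS and 0.000857 to 0.17 for AKR1B1, at 6 h 0.0102 to 0.91 and 0.0156 to 0.551, and with MeAIB 0.0133 to 0.136 for COX7A2 and 0.0133 to 0.12 for MRPS28.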

Other observations

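No test in this part was chosen only after the result was seen. In mRNA with MeAIB, several lists passed at the preset correlation with small median changes, while few members passed. Among the lists given here, only initiation factors also passed with an estimated correlation. Of 79 ribosomal proteins, 0 rose, 1 fell and 78 did not pass (median -0.10, camera adjusted p = 4.1e-16, and adjusted p = 0.379 with an estimated correlation). Of 24 replication genes, 0 rose, 0 fell and 24 did not pass (0 and 5 adjusted over the list alone, median -0.11, camera adjusted p = 3.57e-06, and adjusted p = 0.113 with an estimated correlation), and of 26 initiation factors, 0 rose, 0 fell and 26 did not pass (median -0.08, camera adjusted p = 0.00121 and 0.0265 with an estimated correlation). Of 22 immediate early genes, 3 rose, 0 fell and 19 did not pass (10 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 1.17e-07, and adjusted p = 0.0577 with an estimated correlation), with CYR61 and the transcription factor EGR1 among those that rose. The EGR1 call (0.82 ± 0.154, adjusted p = 0.0218) ended without 5 of the 8 libraries, and its adjusted p was 0.000134 to 0.127 over all alternatives. With Torin1 the lists of polyamine genes (9 measured, 0 called by edgeR, median -0.09, camera adjusted p = 0.00852, and adjusted p = 0.163 with an estimated correlation) and of heat shock genes (19 measured, 0 called, median -0.08, camera adjusted p = 0.00397, and adjusted p = 0.269 with an estimated correlation) passed in mRNA only at the preset correlation, with no member past the threshold, so neither group is taken as changed.

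Each comparison of 4 and 4 libraries was also made for all 35 splits of the 8 libraries, with only those 2 conditions fitted. In mRNA the real split gave 1280 genes at 1 h (highest other 1), 7328 at 6 h (1), 6396 between them (2) and 9 with MeAIB (1). There 1 of 35 splits, the real one, was as large, the smallest share that 35 splits can give. With MeAIB 8 of those 9 genes were among the 65 called in the fit of all libraries. With Torin1 the real split gave 1 gene and the highest other 2, and 11 of 35 splits gave as many, so chance is not excluded. That fit held 0 of the 8 rises called in the fit of all libraries, so the splits could not test those. For Torin1 against MeAIB the real split gave 0 and the highest other 1, so the splits could not test the 54 genes called in the fit of all libraries. In footprints the real splits gave 7938 at 1 h (0), 6733 at 6 h (0), 7404 between them (0), 2635 with Torin1 (3), 1473 with MeAIB (1) and 2656 between the drugs (2). In translation they gave 7357, 3245, 5912, 1158, 439 and 1607 in the same order, with 0 as the highest other each time. In each of these too, only the real split was as large. Mixed splits place any difference between conditions within the groups, which lowers their counts, so 35 splits cannot exclude chance.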
